A study of Rattus norvegicus with 12 samples.

How the data were processed

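Total RNA from primary cultures of rat striatal neurons, kept 4 weeks in vitro, was hybridised as biotin-labelled target to 12 Affymetrix rat expression arrays, 1 array per sample. Per the labels, 6 samples had received a lentivirus carrying the TRE-Htt-N853-18Q construct and 6 the TRE-Htt-N853-82Q construct, in both cases 4 weeks earlier. Groups and replicate numbers were taken from the sample labels. The labels record the same RNA extraction kit throughout, and for 18Q replicate 1 also an ethanol precipitation. They do not say whether samples of a group came from separate cultures. Tests of single genes and of list mean levels use the spread between these samples, which may be partly technical.

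The deposited values are log2 expression summaries, 1 per probe set and array, made by the authors with RMA from the affy package, per the submitters' processing notes. Versions, background settings and the order of steps are not given in the sources used here. RMA adjusts the background, equalises the arrays and summarises the probes of a set, so small overall differences in RNA amount between arrays are removed before the values are deposited, and low signals are compressed towards a common floor. The medians of the 12 arrays lay between 4.06 and 4.15. Scanner files, detection calls and scan dates were not used here, so no batch was tested, and whether a probe set lies above background was judged only from its level among all probe sets. The number of arrays limits the precision.

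Affymetrix control probe sets, 57 in all, were left out of the tests, which leaves 31042. Gene names came from the platform annotation, with symbols updated through the gene identifiers of the rat GRCr8 RefSeq table. Of the tested probe sets, 20826 carried 1 symbol, 436 carried several and 9780 are unnamed here. No gene is named from a probe set with several symbols. The named probe sets stood for 14217 genes, each represented in gene lists by its probe set with the highest mean over all 12 arrays.

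The comparison was a 2-group linear model in limma 3.58.1 under R 4.3.3, with moderated two-sided tests, no covariate, and Benjamini-Hochberg adjustment over all tested probe sets at a threshold of 0.05. Changes are 82Q minus 18Q on the log2 scale, with the standard error (SE) of the fit; levels are means with the standard deviation (SD) between arrays. Genes were named by a rule: the 12 highest and 12 lowest changes among genes that, at their brightest probe set (the highest mean over all 12 arrays), passed the threshold and had a mean in the higher group at or above the median of all probe sets (4.09), up to 4 members of each gene list with the smallest p, and Htt with reference genes. The 25 gene lists were tested against the other named genes with camera at a preset inter-gene correlation of 0.01, adjusted over the 25 lists. At that preset value camera's p rests on the spread between genes and the assumed correlation, not directly on the spread between samples. The lists were tested again with an estimated correlation. Tests against no change, which make no comparison with other genes, were fry and an exact permutation test of each list's mean level over all 924 assignments of arrays to groups, whose smallest two-sided p is 0.00216. The design, the lists, the naming rule and the alternatives were fixed before the data were examined, except for alternatives described as chosen after seeing the data.

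Alternatives covered median centring and quantile normalization of the deposited values, filters on dim probe sets at the median and at the 25th percentile, a variance prior with an intensity trend or made robust, array weights, a block for the replicate number, 1 probe set per gene, the mean of all probe sets of a gene for the lists, and leaving out each array in turn. Chosen after seeing the data were a fit without 18Q replicate 1 and 82Q replicate 5, and a fit with the SD of each array's log2 values as a covariate. The fit was tested on simulated data for 31042 probe sets. Changes were planted only at or above the median level, and the noise was independent between probe sets. Of 67 changed by 0.3 on the log2 scale 37.3% were recovered, of 67 changed by 0.6 94.0%, and of 66 changed by 1 98.5%. There were 5 false calls among 158. These rates do not cover dimmer probe sets or noise shared between genes or carried by single arrays.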

Results

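The series asks how a fragment of huntingtin with an expanded glutamine repeat alters gene expression in striatal neurons, as an in vitro model of Huntington's disease. Primary rat striatal neurons were infected with lentivirus expressing an N-terminal huntingtin fragment (N853) with 18 glutamines, a repeat of normal length, or with 82 glutamines, a repeat in the disease range. After 4 weeks, expression was measured in 6 samples of each kind, called 18Q and 82Q. Cultures without virus were not analysed here, so each value compares the expanded with the normal repeat. The arrays resembled one another closely: Pearson's r between pairs, across probe sets, which are not independent replicates, ran from 0.986 to 0.995. Pairs that held 82Q replicate 5 gave 0.986 to 0.991 and the others 0.991 to 0.995.

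Transcripts of Sst, Npy, Inhba, Igf1 and Pdyn fell in 82Q. Sst, the precursor of somatostatin, had a log2 level of 9.26 ± 0.15 in 18Q and 8.03 ± 0.18 in 82Q (SD, n = 6 each), or 42.7% of the 18Q level, a change of -1.23 (SE 0.08; limma adjusted p = 2.2e-07). Npy, the precursor of neuropeptide Y, fell from 7.51 ± 0.15 to 6.56 ± 0.17, to 51.9% of the 18Q level (limma adjusted p = 4.5e-06). Inhba, which encodes the activin A subunit, fell from 6.13 ± 0.12 to 4.97 ± 0.22, to 44.7% (limma adjusted p = 8.4e-07), and Igf1, a growth factor, from 6.18 ± 0.14 to 5.28 ± 0.21, to 53.6% (limma adjusted p = 2.3e-05). Pdyn, the prodynorphin gene of striatonigral projection neurons, fell by 0.53 on the log2 scale (SE 0.09; limma adjusted p = 0.0132), to 69.1%. All 6 arrays of 82Q lay below all 6 of 18Q for Sst, Npy, Inhba and Igf1.

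Setd5 changed by -0.91 (SE 0.13; limma adjusted p = 0.00197), Nell1, a secreted protein, by -0.72 (SE 0.10), and Sertm1 by -0.68 (SE 0.07). Opn3, an opsin, and Hpse, the heparan sulfate-degrading enzyme heparanase, both changed by -0.58, with SE 0.08 and 0.10. Lamb1, a laminin chain of the basement membrane, changed by -0.54 (SE 0.06), and C1ql3, a secreted synaptic protein, by -0.49 (SE 0.08). The 1 gene that rose was Stn1, a subunit of the telomere-capping CST complex, from 5.91 ± 0.11 to 6.43 ± 0.08, to 143% of the 18Q level (limma adjusted p = 4.6e-04). Among genes with several probe sets, 2 of 3 passed for Igf1. For Setd5 1 of 3 passed, the others standing at -0.13 and -0.09. The other probe set stood at 0.02 for Inhba, -0.16 for Pdyn, -0.05 for C1ql3 and 0.06 for Stn1. For these genes it lay near the median level, in the 46.2 to 56.3 percentile of probe sets. Low signals can be compressed there, yet the second Igf1 probe set passed at -0.70 (SE 0.09) at a like level (51.0 percentile). The level alone therefore does not set the disagreeing probe sets aside, and they do not back the changes. The changes of Inhba, Pdyn, C1ql3, Stn1 and Setd5 each rest on 1 probe set.

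**Figure D1:**
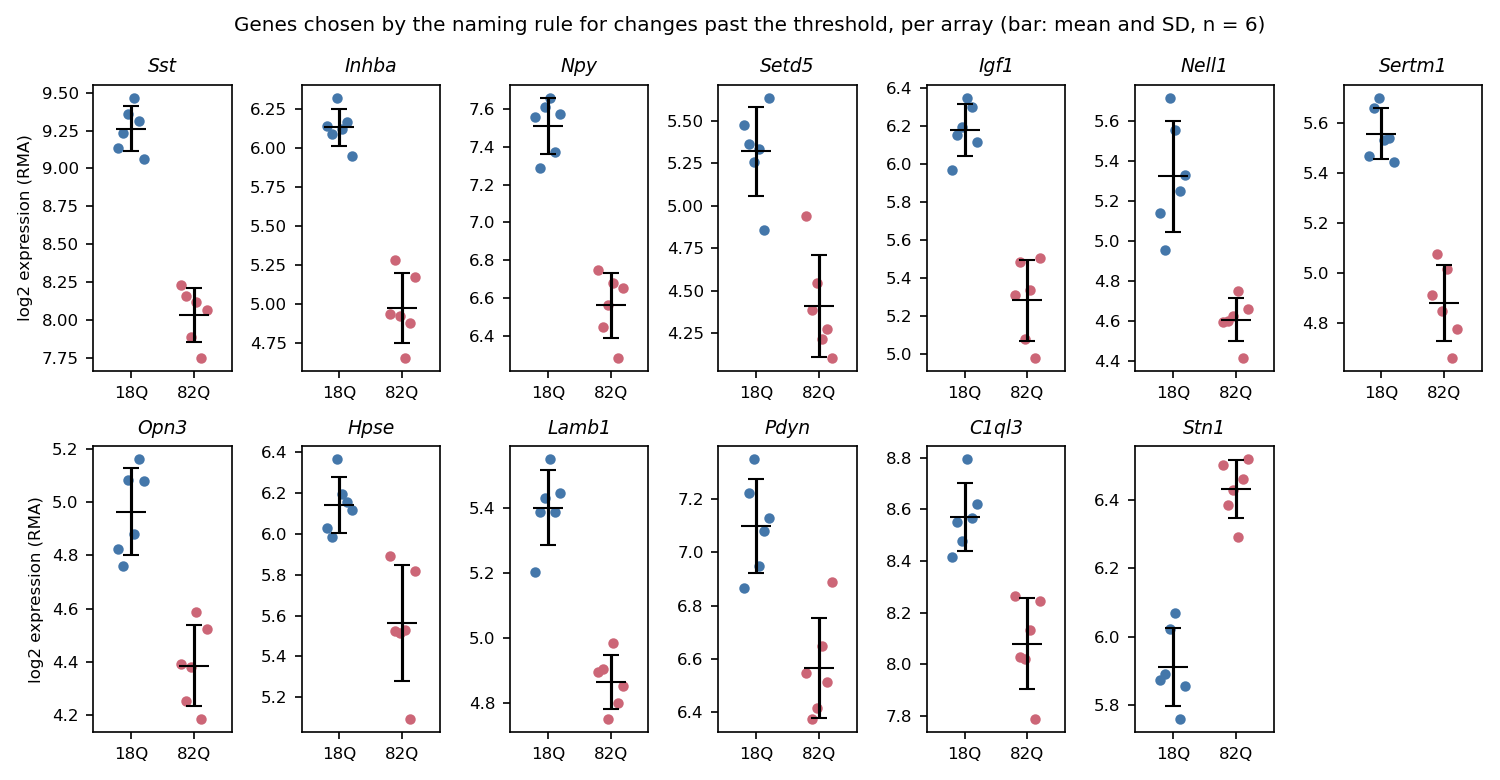
Log2 expression (RMA values, vertical axis, scaled per gene) of 13 genes past the threshold, chosen by the naming rule for the highest and lowest changes at each gene's brightest probe set, on each of the 6 arrays of 18Q (blue) and 82Q (red). The bar is the mean and the whiskers the SD. For Sst, Npy, Inhba and Igf1 every 82Q array lies below every 18Q array, and for Stn1 every 82Q array lies above.

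Over the whole array, 40 of 31042 probe sets passed the threshold, 39 lower and 1 higher in 82Q. Of these 28 carried 1 symbol, for 27 genes, and 12 are unnamed here. Their changes ran from 0.30 to 1.23 in size, and 3 reached 1. At an unadjusted p under 0.05 there were 2230 probe sets, 1302 lower and 928 higher, where 1552 would pass by chance. The count moved with single arrays: it was 21 without 18Q replicate 3, 23 without 18Q replicate 5, 82Q replicate 2 or 82Q replicate 3, and 93 without 82Q replicate 1. Among the named genes, Hpse missed the threshold without 18Q replicate 3, 4, 5 or 6 or 82Q replicate 2, 3 or 4, with a highest adjusted p of 0.101, and Pdyn without 18Q replicate 3 or 82Q replicate 2 or 3, with a highest of 0.0568.

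**Figure D2:**
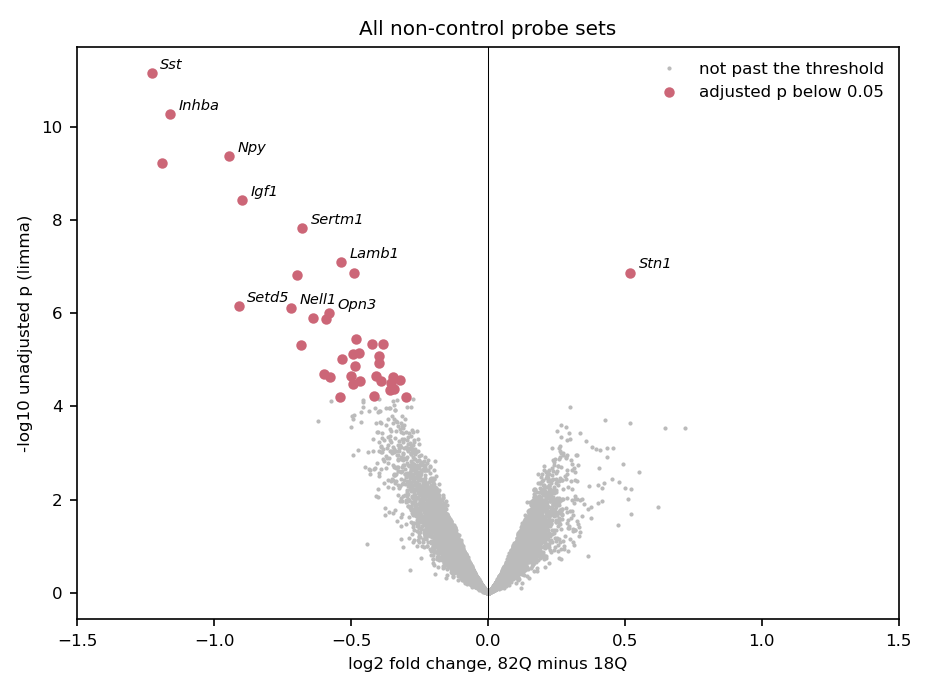
Log2 fold change (82Q minus 18Q, horizontal axis) against the negative log10 of the unadjusted limma p (vertical axis) for 31042 probe sets. Red points are the 40 past the adjusted threshold, 39 of them on the left; genes chosen by the naming rule with the smallest p are labelled.

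Interneuron markers were lower in 82Q as a list: of 14 measured, Sst and Npy fell, and adjusted over the list alone Th did as well (-0.43, SE 0.12). The median change was -0.08, and camera gave an adjusted p of 3.8e-06, with 0.00705 under an estimated correlation. The list's mean level was lower on all 6 arrays of 82Q than on any of 18Q (exact permutation p = 0.00216, the smallest possible; 0.0271 adjusted over 25 lists). Sst and Npy weigh heavily in the mean change of -0.23, and the permutation test was not repeated without them. Without Sst and Npy, a subset chosen after seeing their values, the other 12 had a median of -0.07 and camera p = 0.0188, with p = 0.0328 under an estimated correlation. On the same arrays 16 of 20 astrocyte markers had a positive change, with a median of 0.23, and a link between these lists was not tested.

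Genes that mark striatal projection neurons, the cells most affected in Huntington's disease, were also lower as a list. Camera gave an adjusted p of 1.6e-05, and the adjusted p was 0.0762 with an estimated correlation. Of 45 measured, 31 had a negative change at their brightest probe set, where Pdyn passed over all probe sets and 8 were lower adjusted over the list alone, with a median of -0.05. Those 8 included Penk, the enkephalin precursor of striatopallidal neurons (-0.34, SE 0.08), Arpp21 (-0.34, SE 0.09) and Neto2 (-0.36, SE 0.07). Neto2 also passed over all probe sets at its other probe set (-0.60, SE 0.11, limma adjusted p = 0.0242). Not all members fell, and 14 of the 45 had a positive change. At an unadjusted limma p under 0.05, 13 members were lower and 1 was higher, Drd2 (0.17, SE 0.07), below the median level. Ppp1r1b stood at -0.08, Ptpn5 at 0.03, Rasd2 at 0.02 and Drd1 at -0.008. Drd2 and these genes were named after their values were seen. The mean level of the list was lower on all 6 arrays of 82Q than on any of 18Q (exact permutation p = 0.00216; 0.0271 adjusted over 25 lists). On the same arrays the median change of astrocyte markers was 0.23, of the opposite sign. The mean change of the striatal list was -0.09 and that of pan-neuronal markers -0.06. The pan-neuronal interval over arrays, -0.21 to 0.09, holds both the striatal mean and no change. A fall of striatal genes in particular was therefore not told apart from a like fall of neuronal genes in general. The 2 lists were not tested against each other.

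At the preset correlation 5 more lists shifted lower, none with a member past the threshold over all probe sets at its brightest probe set. In 23 of 100 splits of the arrays, the real grouping included, 9 or more lists passed, so the number of shifted lists is not unusual. Genes of cholesterol biosynthesis had a median of -0.13 over 20 measured, 18 of them negative. Adjusted over the list alone Cyp51 (-0.27, SE 0.08) and Idi1 (-0.30, SE 0.09) were lower; the camera adjusted p of 6.0e-07 became an adjusted p of 0.180 with an estimated correlation. The list of voltage-gated ion channels, which also holds potassium channels of other kinds such as Kcnj6, had a median of -0.03 over 46. The potassium channel genes Kcnd3 (-0.33, SE 0.07), Kcnj6 (-0.40, SE 0.09), Kcnd2 (-0.25, SE 0.06) and Kcnc1 (-0.23, SE 0.06) were lower adjusted over the list alone. The list's adjusted p of 0.0160 became an adjusted p of 0.120 with an estimated correlation, 0.106 without 82Q replicate 1 and 0.0546 among probe sets at or above the median level. Glutamate and GABA receptor and postsynaptic genes had a median of -0.04 over 36, with Gad1, a GABA-synthesising enzyme (-0.31, SE 0.08), and Gabra2 (-0.43, SE 0.12) lower adjusted over the list alone (camera adjusted p = 0.00556; adjusted p = 0.362 with an estimated correlation). Calcium handling genes had a median of -0.06 over 36, with Rcan2, a calcineurin regulator whose other probe set passed over all probe sets, at -0.32 (SE 0.08) lower adjusted over the list alone (camera adjusted p = 2.6e-04; adjusted p = 0.412 with an estimated correlation). Immature neuron markers had a median of -0.10 over 9, with Sox4 (-0.38, SE 0.10) and Nes (-0.19, SE 0.06) lower adjusted over the list alone (camera adjusted p = 0.00556; adjusted p = 0.242 with an estimated correlation).

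Astrocyte markers and respiratory chain genes shifted higher at the preset correlation. For astrocyte markers the camera adjusted p of 1.6e-05 became an adjusted p of 0.385 with an estimated correlation, and for respiratory chain genes 0.00975 became an adjusted p of 0.735. Of 20 astrocyte markers, 16 had a positive change and the median was 0.23; 0 passed limma's threshold over all probe sets and 9 had an unadjusted p under 0.05, 8 of them higher. Adjusted over the list alone 6 were higher, among them Glul (0.42, SE 0.13), Gja1 (0.42, SE 0.13), Ntsr2 (0.50, SE 0.16) and, named after its value was seen, Gfap (0.62, SE 0.23), and Aqp4 (-0.23, SE 0.07) was lower. The mean level of the markers differed widely between 82Q arrays, from -0.27 on replicate 5 to 0.42 on replicate 1 relative to all 12 arrays, and 3 of the 6 lay above every 18Q array (exact permutation p = 0.0996). Respiratory chain and mitochondrial biogenesis genes had a median of 0.04 over 61 with no member past either adjustment; 1, Ppargc1a at -0.18, had an unadjusted limma p under 0.05. The call for that list was lost without 18Q replicate 1 (0.561), 18Q replicate 6 (0.0747), 82Q replicate 1 (0.175), 82Q replicate 4 (0.0869) or 82Q replicate 6 (0.0932), and without both 18Q replicate 1 and 82Q replicate 5 (0.232), a setting chosen after seeing the data.

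**Figure D3:**
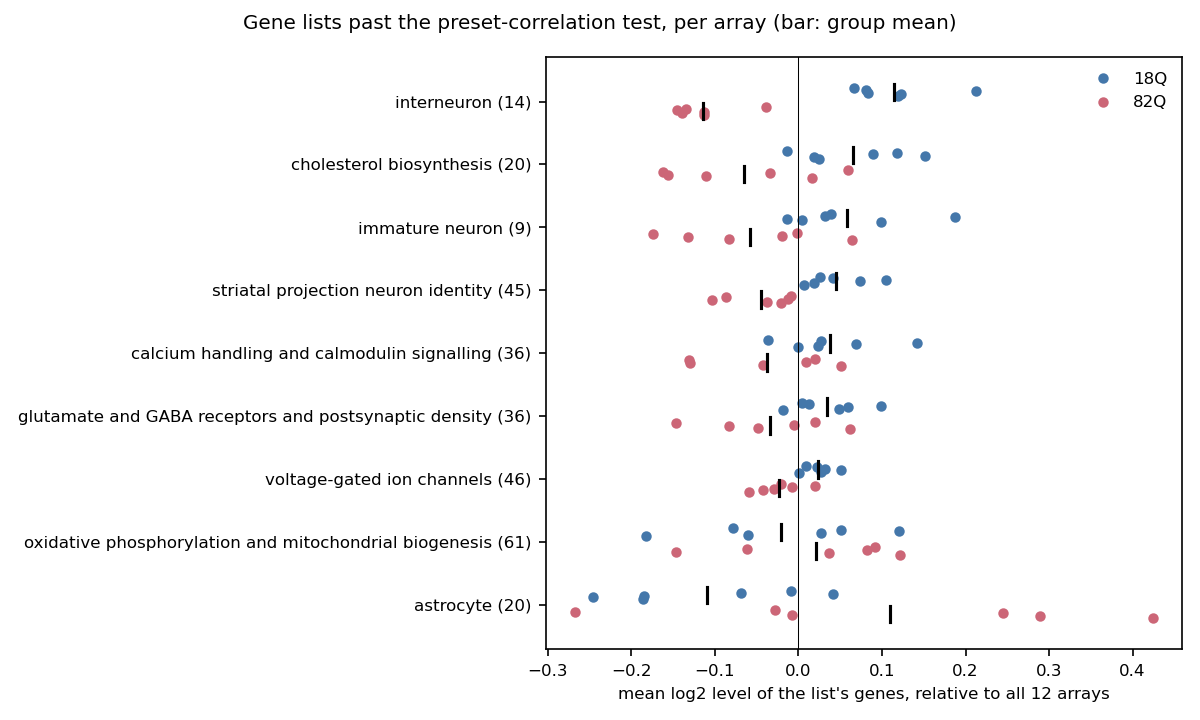
Mean log2 level of the genes of each list relative to all 12 arrays (horizontal axis) on each array of 18Q (blue) and 82Q (red), for the 9 lists past camera at the preset correlation, with the number of genes measured in brackets; bars are group means. The interneuron and striatal projection neuron lists do not overlap between groups, while astrocyte markers spread from -0.27 to 0.42 within 82Q.

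The other 16 lists did not pass. Pan-neuronal markers had a median of -0.03 over 18, with Nefm (-0.33, SE 0.08), Rbfox3 (-0.29, SE 0.09) and Celf4 (-0.25, SE 0.08) lower adjusted over the list alone (camera adjusted p = 0.0822); leaving out 18Q replicate 1 or 6 or 82Q replicate 1, 4 or 6 brought the list past the threshold, at 0.00200 to 0.0355, as did quantile normalization (0.0170), the mean of all probe sets of a gene (0.0238) and, chosen after seeing the data, leaving out both 18Q replicate 1 and 82Q replicate 5 (0.0201), so 8 of 25 alternatives. With an estimated correlation its adjusted p was 0.735. Activity-regulated genes had a median of -0.00177 over 31. Their only member past the threshold over all probe sets was Inhba, and Jun (-0.45, SE 0.13), Nr4a3 (-0.40, SE 0.12) and Dusp1 (-0.34, SE 0.11) were lower adjusted over the list alone; camera gave 0.249, and 0.0485 among probe sets at or above the median level. Against no change, fry's test for change in either direction gave an adjusted p of 3.7e-05. Synaptic vesicle genes had a median of -0.01, with Cplx2 (-0.27), Bsn (-0.21) and Rab3b (-0.25) lower and Syt5 (0.18) higher adjusted over the list alone (camera adjusted p = 0.376). Microglial and macrophage markers had a median of 0.04, with Gpnmb (0.65, SE 0.15) higher adjusted over the list alone (camera adjusted p = 0.113); without 18Q replicate 1 or 6 or 82Q replicate 1 or 2 the list passed, at 0.0115 to 0.0442. Interferon response genes had a median of 0.03 (camera adjusted p = 0.0699) and passed without 18Q replicate 1, 2 or 6 or 82Q replicate 1 or 6, at 0.0115 to 0.0430, with the replicate number as a block (0.0479), and among probe sets at or above the median level (0.0485) or the 25th percentile (0.0363), so in 8 of 25 alternatives. Fibroblast markers had a median of 0.09 (camera adjusted p = 0.134; 0.0255 without 18Q replicate 3).

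No member passed either adjustment in the lists of stress and housekeeping pathways. The median was -0.02 for heat shock genes (camera adjusted p = 0.305), 0.01 for p53 and apoptosis genes (0.305), 0.02 for proteasome subunits (0.858) and 0.02 for inflammatory genes (0.487). Unfolded protein response genes had a median of -0.02 and a mean of 0.01, so these differ in sign (camera adjusted p = 0.378); Ddit3, a transcription factor of that response, stood at -0.24 (SE 0.07; limma adjusted p = 0.207). Cortical glutamatergic markers had a median of -0.02 (0.560), oligodendrocyte markers 0.00885 with a mean of -0.00231 (0.841), endothelial markers 0.02 (0.444), ependymal markers 0.03 (0.305) and dividing cell markers -0.02 (0.305).

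Htt itself, at its brightest probe set, had a log2 level of 6.12 ± 0.10 in 18Q and 6.14 ± 0.13 in 82Q (SD, n = 6 each), with differences of 0.11 and -0.08 at its other probe sets. Whether any of these probe sets can read the viral fragment is not known, so the values do not check the labels. Of the reference genes, Hprt1 differed by 0.07 (SE 0.07) and Tbp by -0.06 (SE 0.07), both within the spread between arrays. Actb and Gapdh were not analysed here as genes; the difference between the 3' and 5' control probe sets of actin, a sign of RNA length, was 2.04 ± 0.08 in 18Q and 1.93 ± 0.08 in 82Q (exact permutation p = 0.0433; 0.216 adjusted over 5 array measures, of which none passed).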

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

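The tests on neuron loss, on interneuron number and on hybridization controls below were chosen only after the result was seen. The fall of 39 of 40 called probe sets was set against technical sources first. With the SD of each array's values as a covariate the called probe sets kept a median ratio of 0.969 of their change. That SD hardly differed between groups (1.62 ± 0.03 in 18Q, 1.61 ± 0.04 in 82Q). The covariate could therefore remove little of a group difference, and no conclusion on array spread is drawn from the ratio. After quantile normalization the ratio was 0.970, but the deposited values had already been equalised, so this cannot exclude the authors' normalization, which stays open. Only the real grouping among 100 of the 462 splits of the arrays gave as many as 40 probe sets, the highest other split giving 2. To the resolution of 100 splits, this argues against a chance assignment of arrays to groups as the source of the count. It cannot address a chance difference between cultures, since the labels do not say whether samples of a group came from separate cultures. A batch shared with the groups stays open as well, since no batch or scan label was used here, and an effect of the repeat length is a hypothesis.

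The fall of Sst and Npy, by -1.09 on average, was compared with 2 explanations. A general loss of neurons might give a like fall of pan-neuronal markers. Their mean change was -0.0593 (95% interval -0.21 to 0.09), above -0.54, which is 50% of the Sst and Npy mean. This argues only against a fall of these markers as large as that, relative to other transcripts. A general loss of neurons stays open, since the arrays were equalised and a loss of most cells in a neuron culture could leave relative levels little changed. Fewer cells of the interneuron type that makes both peptides would also lower Nos1 and Chodl. Nos1 stood at 0.11 (SE 0.10) and Chodl at -0.12 (SE 0.10), in opposite directions. Tacr1, a marker outside this test, stood at -0.02, below the median level. The mean change of Nos1 and Chodl was -0.00419 (95% interval -0.22 to 0.21), above -0.54 and so against a like fall of both, at levels in the 61.4 to 66.8 percentile of probe sets. Fewer cells and less transcript per cell still cannot be told apart here: the levels lie below the 75 percentile set as needed to decide, only 2 genes were tested, and without detection calls it is not known whether their probe sets read the transcripts.

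On 82Q replicate 5, the median r with the other arrays was 0.990, and the SD of its values, 1.55, was the lowest of the 12 arrays. Less labelled target against fixed hybridization controls may account for it: over the 12 arrays the controls were brighter where the SD was smaller (Pearson's r = -0.639, permutation p = 0.0249). The relation is weak, as Spearman's rho was -0.378 (permutation p = 0.230) and r was -0.46 without 82Q replicate 5, though -0.62 without the 2 arrays farthest from the median SD. It was the 1 relation computed between array measures, both had been seen before the test was chosen, and no biological explanation was tested.

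The number of gene lists past camera at the preset correlation does not exceed what other groupings give: 23 of 100 splits gave 9 or more lists, the highest other 16. For the striatal projection neuron list, only the real split of 100 gave a camera p as small as 1.9e-06, the smallest other being 4.0e-05, in a split that differs from the real one by exchanging 1 array of each group. To the resolution of 100 splits, this argues against a chance assignment of arrays for that p at the preset correlation only. With an estimated correlation the list had an adjusted camera p of 0.0762.

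Among 284 group values, 13 had 1 array standing apart by Dixon's criterion. Chance gives about 1 in 20, so the number is no more than chance would give. The gap as a share of the group's range is given for each, with a critical value of 0.625. On 18Q replicate 4 these were Foxj1 (0.728), Rbfox3 (0.662), Tbp (0.872) and the hybridization controls (0.648), and on 18Q replicate 1 Kcnc1 (0.703), Msmo1 (0.731) and Nefm (0.683). Single cases were Ttr on 18Q replicate 5 (0.751), Neurod1 on 82Q replicate 3 (0.642), Cldn5 on 82Q replicate 4 (0.696), Psma3 on 82Q replicate 5 (0.686), the p53 list on 82Q replicate 1 (0.635) and the interneuron list on 82Q replicate 6 (0.694).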

How the results depend on the processing

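No result past its threshold changed direction under the alternatives run. The count of 40 probe sets became 102 after quantile normalization, 71 among probe sets at or above the median level, 61 at or above the 25th percentile, 81 with array weights, 26 with 1 probe set per gene, and 193 with array spread as a covariate, an alternative chosen after seeing the data; the filters and the single probe set test fewer features, and for the others the cause was not tested. Leaving out 1 array gave 21 to 93. Of the 40 probe sets, 21 passed in every such fit and all 40 kept their sign. The share of lower calls, 97.5%, was 79.6% without 82Q replicate 5 and 82.9% with the spread covariate. Without both 18Q replicate 1 and 82Q replicate 5, also chosen after seeing the data, 56 passed. Lists past the threshold numbered 9, 1 with an estimated correlation, and 2 with fry, which tests against no change and not against other genes; leaving out 1 array gave 9 to 11. The striatal list had an adjusted p of 0.0762 with an estimated correlation and 8.1e-06 to 1.0e-04 when 1 array was left out. Of the 13 genes the naming rule gave for changes at the brightest probe set, Hpse passed in 15 of 23 settings and Pdyn in 20, the others in all 23, while 12 named genes short of the threshold passed in at least 1 setting. With the replicate number as a block 46 probe sets passed, 4 higher and 42 lower, 30 of them shared. Same-numbered samples did not deviate together (1 of 6 correlations over 0.1, 0 of 6 samples best matched by their own number), so the numbers were not read as pairing. Levels near the median of 4.09 may be compressed by RMA, which limits what dim genes can show, though an Igf1 probe set near it changed by -0.70.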

Other observations

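The tests on neuropeptide precursors and on retinoic acid were chosen only after the result was seen, and all the lists below were written once Sst, Npy and the other called genes were known. Beyond the genes the rule named for the highest and lowest changes, 14 genes passed the threshold, all lower in 82Q. Neto2 and Rcan2 had been named by the rule as list members, at another probe set, and the others are named after their values were seen. Cyp26b1, which encodes a retinoic acid-degrading enzyme, fell by 1.19 on the log2 scale (SE 0.11, limma adjusted p = 4.8e-06) at 1 probe set. It stood at 0.03 at its other probe set, which is its brightest, so the fall rests on 1 probe set. Pnoc, the precursor of nociceptin, fell by 0.40 (SE 0.07), so with Sst, Npy and Pdyn 4 neuropeptide precursors were lower. Pmepa1, a target and inhibitor of TGF-beta signalling, fell by 0.49 (SE 0.06), and the nuclear receptor gene Esrrg by 0.48 (SE 0.08). Msi2 fell by 0.68, Neto2 by 0.60, Rcan2 by 0.47 and Pip4k2a by 0.30 at a probe set other than their brightest. The remaining ones were Ngef (-0.42), Myt1l (-0.41), Tmeff1 (-0.39), Phactr3 (-0.36), Elmo1 (-0.36) and Ift57 (-0.32). The other probe set stood at 0.01 for Myt1l and 0.15 for Phactr3, both dim (4.95 and 20.8 percentile), so each of these falls rests on 1 probe set. For Esrrg and Tmeff1 the other probe set was also lower, at -0.46 and -0.41.

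As a hypothesis, the fall of the 4 precursors could belong to a fall of neuropeptides as a class. A list of 20 further precursors had a mean change of -0.00926 (95% interval over genes -0.05 to 0.03). It excludes nothing, since 15 of the 20 lie below the median level and it leaves out Penk, which was lower adjusted over the striatal list alone (-0.34), so this stays open. For transcripts of 13 genes for dense core vesicle proteins, of which 1 lies below the median level, the mean was 0.0211 (95% interval over genes -0.01 to 0.05, over arrays -0.08 to 0.12), which argues against a fall of these transcripts by 0.15 or more. A weaker retinoic acid response, as a hypothesis for Cyp26b1, stays open: 9 response genes had a mean of 0.00789 (95% interval over genes -0.04 to 0.06), but 6 of them lie below the median level.

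Less activin, from the fall of Inhba, might lower genes that respond to activin and TGF-beta. The 19 measured, without Inhba and Pmepa1, had a mean change of -0.0750 (95% interval over genes -0.14 to -0.01), with camera p = 0.0157 under an estimated correlation and 0.0630 adjusted over the 4 lists of this part. None passed limma's threshold over all probe sets, 3 had an unadjusted p under 0.05, all lower, and 10 lie below the median level. Fst, which encodes the activin-binding follistatin, stood at -0.39, the member with the smallest p. The value met both outcomes set in advance, a camera p under 0.05 for the hypothesis and an interval above -0.15 against it, so the test does not decide, and the hypothesis stays open.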
